A study of Mus musculus with 24 samples.

How the data were processed

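Gene expression was measured by RNA sequencing of 24 libraries of 1000 sorted microglia each, from 12 mice aged 19 months (6 WT and 6 GrnKO, with 3 labelled male and 3 labelled female in each genotype). Every animal gave a lipofuscin-low and a lipofuscin-high library. Per the labels' protocols, brains were dissociated in the presence of actinomycin D and anisomycin, which block transcription and translation, and cDNA was made from polyadenylated RNA with a SMART-Seq 3' kit and Nextera XT and sequenced as single-end reads. Per the submitters' processing notes, the tools used were STAR 2.7.9a, Salmon 1.10.1, edgeR 4.6.2 and R 4.5.1, with the genome build GRCm39. Strand handling in counting is not given in the sources used here. No coordinates are given, because the reference used here is of another build, and gene names are those of the deposited table. Of the tested genes, 12 share a symbol with another tested gene, and none of these is named.

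The authors deposited estimated counts per gene (Salmon), written with 2 significant digits. Of values between 0 and 10, 8.28% were not whole (tolerance 1e-09). A second deposited table holds normalized CPM, which is a signal scaled by library size and normalization factor, also with 2 significant digits: of values over 50 counts, 100% lay within 7 percent of the count divided by library size times factor. The deposited sample sheet gives the authors' own library size and normalization factor (a ratio) of each library. Column sums lay within 0.220% of the deposited library sizes. Of the per-sample columns, 0 matched no sample.

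The design had assumed counts, so the deposited estimated counts were rounded to whole numbers before testing. Of 56980 genes, filterByExpr by group removed 42890 and left 14090. Library sizes were scaled by TMM, whose factors correlated with the deposited ones at r = 0.985 with a largest ratio of 1.05. A quasi-likelihood model was fitted in edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest; R 4.3.3) to all 24 libraries with 1 term per group and the sex label as covariate, and the common biological coefficient of variation was 1.08. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 5 main contrasts were the genotype effect in each bin, the lipofuscin effect in each genotype and their interaction, and the genotype effect was also compared between the labelled sexes in a fit with 8 groups of 3. All tests were 2-sided. Levels in the text are CPM with TMM-scaled library sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

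The 35 gene lists, 12 of them markers of other cell types, were fixed before the data were examined. So were the tests, the alternatives not said to be added and the rule for named genes. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 35 lists within a contrast. It was tested again with the correlation estimated from the data and with fry. Calls adjusted over the list alone are given beside those over all genes. Summed CPM of 16 lists were compared between genotypes by exact permutation and between bins by exact sign flips over animals, adjusted over the 16.

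The text names Grn in every comparison and, in each main contrast, the 8 called genes with the largest positive and the 8 with the most negative fold change among those with a mean of at least 10 CPM in the higher group and a gene symbol that is not a clone or predicted-gene name. It also names, for each list with a called member, up to 3 members of smallest p in the main direction and up to 1 in the other, and for a list discussed without a called member up to 2 of smallest p. In the sex comparison it names the called genes if they number 5 or fewer. Some genes that the rule selects are left out of the text. Genes shared between calls of 2 comparisons, the marker genes of the sex check, Cst3 and the single interaction gene of limma-voom were named after their values were seen.

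The libraries held 12.9 to 46.8 M counts (median 30.5 M), with 1.46 to 9.70% mitochondrial counts (median 2.20%). Changes were simulated at the real depths in 200 genes averaging at least 10 CPM. Of 4-fold changes, 73.1% were recovered for genotype in the low and 71.6% in the high bin. For lipofuscin it was 70.1% in WT and 62.7% in GrnKO. Of 2-fold changes it was 14.9%, 7.46%, 13.4% and 13.4%. Reads carried no molecular identifiers, so counting intervals cover counting error only. Among 60 pairs of libraries of 1 group, 0 were identical, and the smallest chi-square per gene between 2 libraries was 125, so no library was counted as a copy of another.

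Libraries are paired by the animal number in the labels. The deviations of an animal's 2 libraries from their group means correlated with r between -0.0148 and 0.320 (median 0.106, 7211 genes), and 6 of 12 low libraries correlated best with the high library of the same animal; the consensus correlation used for the random block was 0.0872. The main model has no animal term. Alternatives had the animal as a fixed block in edgeR, for contrasts within animals, or as a random block in limma-voom. Further alternatives were DESeq2 1.42.0 and limma-voom, other scalings and filters, no sex covariate, only the groups compared, limma on log2 of the deposited CPM plus 1 or 0.1, and each animal left out in turn. Chosen after seeing the data were counts refined from both deposited tables, library quality weights, a fixed animal block in limma-voom, the test of Grn within animals, the removal of 4 libraries with over 10000 CPM of choroid plexus markers, and settings for the correlation of effects.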

Results

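Gene expression was measured in microglia, the resident macrophages of the brain, from 12 mice aged 19 months. Of these, 6 were wild type (WT) and 6 lacked Grn (GrnKO), the gene of progranulin. Progranulin is a secreted glycoprotein that reaches the lysosome and is processed there into granulins. All carried a humanized transferrin receptor allele on a C57BL/6J background. Cells positive for CD11b and CD45 were sorted from each brain into a low and a high bin of autofluorescence in the 488 nm channel, taken as a measure of lipofuscin. Lipofuscin is the undigested lipid and protein residue that lysosomes gather with age. Each animal therefore gave 2 libraries of 1000 cells. The 24 libraries formed 4 groups of 6 (WT low, WT high, GrnKO low and GrnKO high). The limits of each gate, and whether they were equal in both genotypes, are not given in the sources used here. Total counts per library, in M (mega) counts, ranged from 12.9 to 38.4 M in WT low, 20.7 to 42.2 M in WT high, 20.3 to 46.4 M in GrnKO low and 25.1 to 46.8 M in GrnKO high. Between 10978 and 12978 genes per library had at least 10 counts. Levels are counts scaled by library size (CPM) as mean ± SD over the 6 animals of a group, each an independent animal. Fold changes are on the log2 scale (log2FC), with their standard error (SE) where given. Adjusted p are from edgeR unless another tool is named.

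Grn (ENSMUSG00000034708) separated the genotypes in each of the 24 libraries. It lay between 439 and 1477 CPM in WT and between 0.520 and 20.3 CPM in GrnKO, and 0 libraries went against their genotype label. In the low bin it was 5.93 ± 7.49 CPM in GrnKO low against 625 ± 123 CPM in WT low, log2FC -6.78, SE 0.919, edgeR adjusted p = 0.000576. In the high bin it was 4.68 ± 6.57 CPM in GrnKO high against 933 ± 337 CPM in WT high, log2FC -7.78, SE 0.963, edgeR adjusted p = 0.000282. Between the bins Grn was not called by edgeR, with a log2FC from low to high of 0.58 in WT (adjusted p = 0.935) and -0.42 in GrnKO (adjusted p = 0.997). Within animals it was higher in the high library of 6 of 6 WT animals (mean log2 0.53, SD 0.295, exact sign-flip p = 0.0313, the smallest that 6 pairs allow) and of 2 of 6 GrnKO animals (exact p = 0.375). With the animal as a fixed block in edgeR its adjusted p was 0.308 in WT and 0.786 in GrnKO. The residual Grn counts in GrnKO ranged from 15 to 480 per library.

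The transcripts of the sex chromosomes opposed the sex labels in all 12 animals. Xist, the RNA that silences an X chromosome in female cells, lay between 701 and 2273 CPM in libraries labelled male and between 1.01 and 2.21 CPM in libraries labelled female. The sum of 4 Y-linked genes lay between 0.275 and 1.08 CPM in libraries labelled male and between 60.4 and 119 CPM in those labelled female. The labels still divide the animals into 2 classes of 3 per genotype. This class was the covariate of the main model, which gives the same genotype and lipofuscin effects whichever class is called male. Animals are called "labelled male" or "labelled female" from here on.

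**Figure D1:**
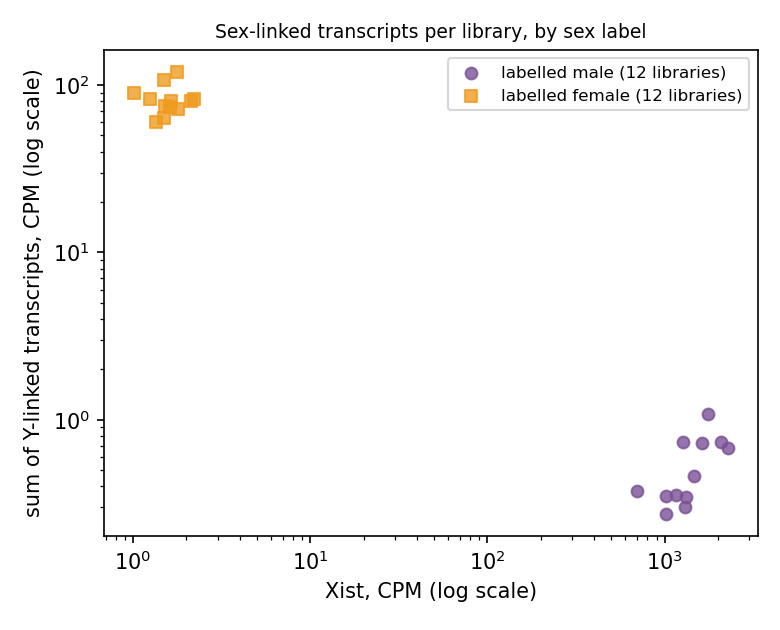
Each point is 1 of the 24 libraries, with Xist on the horizontal and the sum of 4 Y-linked transcripts on the vertical axis (both CPM, log scale), by sex label. The 12 libraries labelled male lie at 701 to 2273 CPM of Xist and the 12 labelled female at 60.4 to 119 CPM of the Y-linked sum.

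The first question was what loss of Grn changed in microglia with little autofluorescence. In the low bin, 38 genes rose and 8 fell in GrnKO among 14090 tested (n = 6 animals per group). Gpnmb (ENSMUSG00000029816), a glycoprotein of lysosomes in lipid-laden macrophages, had the largest fold of the named genes that rose (273 ± 122 CPM in GrnKO low against 1.62 ± 1.02 CPM in WT low, log2FC 7.36, SE 0.454, edgeR adjusted p = 5.60e-11). GrnKO exceeded every WT library in 6 of 6. Fabp5 (ENSMUSG00000027533), a fatty acid carrier, rose from 138 ± 42.2 to 1017 ± 368 CPM (log2FC 2.86, SE 0.195, adjusted p = 2.82e-10). Igf1, a growth factor released by activated microglia, rose from 17.3 ± 5.80 to 103.6 ± 21.4 CPM (log2FC 2.59, SE 0.230, adjusted p = 7.74e-08).

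Of the 32 tested genes of the disease-associated microglia list, the programme of phagocytic microglia around plaques and debris, 12 rose and 0 fell, or 22 when adjusted over the list alone (camera adjusted p = 2.93e-49, adjusted p = 0.000163 with an estimated correlation), and the median log2 fold change was 0.81. The summed list stood at 88544 ± 10217 CPM in GrnKO and 42212 ± 7929 CPM in WT (exact permutation p = 0.00216, adjusted 0.0115 over 16 sums). Besides Gpnmb, Fabp5 and Igf1, these included Cst7, an inhibitor of lysosomal cysteine proteases (743 ± 108 against 152 ± 71.1 CPM, log2FC 2.30, adjusted p = 6.32e-06). Apoe, the main lipid carrier of the brain, rose (16988 ± 3866 against 5709 ± 2485 CPM, log2FC 1.56, adjusted p = 0.000771), and so did Cd63, a membrane protein of late endosomes (7536 ± 838 against 2867 ± 785 CPM, log2FC 1.40, adjusted p = 8.59e-07). Tyrobp, the signalling adaptor of TREM2, rose as well (8086 ± 2442 against 4091 ± 406 CPM, log2FC 1.00, adjusted p = 0.0156). Among genes outside the fixed lists, Gpx3, a secreted glutathione peroxidase (191 ± 46.6 against 12 ± 9.41 CPM, log2FC 4.04, adjusted p = 0.00358), was among the 8 largest rises. So were Ccl8, a chemokine (211 ± 133 against 33.5 ± 20.1 CPM, log2FC 2.66, adjusted p = 0.00718), and Hpse, the heparan sulfate-degrading enzyme heparanase (28.4 ± 9.56 against 0.887 ± 1.78 CPM, log2FC 5.57, adjusted p = 0.0155).

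Lysosomal genes passed the list test at its preset correlation. Of 45 tested hydrolases and membrane proteins, 4 rose and 0 fell (13 rose when adjusted over the list alone; camera adjusted p = 8.18e-10, adjusted p = 0.0592 with an estimated correlation). Among them were the proteases Ctsd (12202 ± 3764 against 4427 ± 1491 CPM, log2FC 1.46, adjusted p = 0.00577) and Ctsb (10127 ± 2010.0 against 3924 ± 1239 CPM, log2FC 1.37, adjusted p = 0.00205). Of 18 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 2 rose (6 adjusted over the list alone; camera adjusted p = 4.61e-08, adjusted p = 0.00234 with an estimated correlation). These were Atp6v0d2, a subunit of osteoclasts and macrophages (12.6 ± 7.03 against 0.0856 ± 0.171 CPM, log2FC 7.23, adjusted p = 0.00250, with 3 WT libraries at 0 counts), and the common subunit Atp6v1f (816 ± 136 against 499 ± 67.2 CPM, log2FC 0.72, adjusted p = 0.0398). The list of BMP and ganglioside catabolism, the breakdown of lysosomal lipids, had a median of 0.37 and 0 members past the threshold over all genes (4 adjusted over the list alone; camera adjusted p = 0.00764, adjusted p = 0.279 with an estimated correlation). Within it the phospholipase-like Pld3 stood at 306 ± 84.1 against 92.1 ± 57.7 CPM (adjusted p = 0.0721) and the hexosaminidase subunit Hexa had a log2FC of 0.74 (adjusted p = 0.136).

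Lipid-handling genes of the LXR and lipid droplet list had 2 members that rose (Apoe and Fabp5), 0 that fell and 3 when adjusted over the list alone (camera adjusted p = 0.00904, adjusted p = 0.0276 with an estimated correlation). This call ended without animal 5 (adjusted p = 0.0606). Iron storage genes rose: 2 of 15 iron-handling genes passed over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000314, adjusted p = 0.0146 with an estimated correlation). They were the ferritin chains Fth1 (23121 ± 4138 against 12331 ± 2075 CPM, log2FC 0.90, adjusted p = 8.63e-05) and Ftl1 (5485 ± 851 against 3019 ± 731 CPM, log2FC 0.86, adjusted p = 0.00807). Of 22 genes of glycolysis and hypoxia, 1 rose, pyruvate kinase Pkm (375 ± 101.8 against 143 ± 32.8 CPM, log2FC 1.39, adjusted p = 0.00577). In all, 11 rose when adjusted over the list alone (camera adjusted p = 1.60e-10, adjusted p = 0.00992 with an estimated correlation). Cytosolic ribosomal protein genes had positive folds in 32 of 33, with a median of 0.39, 0 past the threshold over all genes and 17 adjusted over the list alone (camera adjusted p = 2.07e-13, adjusted p = 0.0540 with an estimated correlation). The nuclear genes of oxidative phosphorylation had a median of 0.25 (camera adjusted p = 0.000901, adjusted p = 0.366 with an estimated correlation). Cell cycle genes had a median of 1.04 (camera adjusted p = 0.000214, adjusted p = 0.268 with an estimated correlation; Mki67, a proliferation marker, 7.80 ± 7.16 against 0.709 ± 1.13 CPM, adjusted p = 0.201). Phagocytic and scavenger receptors had 0.11 (camera adjusted p = 0.0171, adjusted p = 0.0592 with an estimated correlation). The MHC class I list had a median of 0.39 (camera adjusted p = 0.0257, adjusted p = 0.279 with an estimated correlation). It did not pass without animals 1, 2, 9 or 10 (adjusted p of up to 0.380 over the alternatives).

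Fewer genes fell. Cxcl13, a B cell chemoattractant, fell from 139 ± 169 to 4.83 ± 5.68 CPM (log2 fold change -4.74, adjusted p = 0.0237). WT animal 11 alone held 473 CPM, and the adjusted p in limma-voom was 0.275 without a block and 0.273 with the animal as a random block. Of the homeostatic list, the genes of resting microglia, 1 fell (4 adjusted over the list alone). The list's median was -0.28 (camera adjusted p = 0.00468, adjusted p = 0.279 with an estimated correlation). Its summed level did not differ measurably, with 82697 ± 13029 CPM in GrnKO and 82317 ± 15688 CPM in WT (exact permutation p = 0.918, adjusted 0.959 over 16 sums). The lysosomal protease Ctso (68.3 ± 12.8 against 131 ± 28 CPM, log2FC -0.94, adjusted p = 0.0237) fell. So did the chromatin remodelling ATPase Smarca2 (21.5 ± 9.59 against 62.6 ± 12.6 CPM, log2FC -1.54, adjusted p = 0.0136) and the RNA-binding Zfp36l2 (91.4 ± 25.4 against 210.3 ± 67.4 CPM, log2FC -1.21, adjusted p = 0.0312). Filip1l (15.8 ± 5.33 against 47.2 ± 13.3 CPM, log2FC -1.58, adjusted p = 0.0120) and Elmo1, a regulator of engulfment (62 ± 15.3 against 112 ± 20.7 CPM, log2FC -0.85, adjusted p = 0.0112), fell too. Immediate-early genes had a median of -0.21 and a mean of 0.05, of opposite sign (camera adjusted p = 0.0356, adjusted p = 0.279 with an estimated correlation), 0 past the threshold over all genes and 1 up and 4 down adjusted over the list alone. The call ended without animals 3, 5, 6, 7, 8 or 10 (adjusted p of up to 0.192 over the alternatives). Mitochondrially encoded transcripts were lower in 13 of 13, median -0.54 (camera adjusted p = 0.0105, adjusted p = 0.557 with an estimated correlation). The call was lost without animals 1 or 2 and in limma-voom (camera adjusted p = 0.0654 without a block, 0.0582 with the animal as a random block). Without the 4 libraries highest in choroid plexus markers the list turned to higher in GrnKO (camera adjusted p = 0.657). WT animal 1 had 9.70% mitochondrial counts against a median of 2.20% over all libraries.

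Markers of other cell types also differed between genotypes in the low bin. The summed T and NK cell markers were 756 ± 281 CPM in GrnKO and 242 ± 122 CPM in WT (exact permutation p = 0.00216, adjusted 0.0115 over 16 sums). The list's median log2 fold change was 1.84 (camera adjusted p = 8.71e-08, adjusted p = 0.0592 with an estimated correlation). Nkg7, a granule protein of cytotoxic lymphocytes, stood at 237 ± 113 against 63.5 ± 31 CPM (adjusted p = 0.275). Haemoglobin and other erythrocyte markers summed to between 54.5 and 37593 CPM in GrnKO low against 4.68 to 37.8 CPM in WT low (exact permutation p = 0.00216, adjusted 0.0115 over 16 sums). Of 5 genes, 0 were past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 1.54e-07, adjusted p = 0.0592 with an estimated correlation). Astrocyte markers were lower in 12 of 12 genes, median -1.57, 0 past the threshold over all genes and 7 adjusted over the list alone (camera adjusted p = 7.27e-07, adjusted p = 0.0718 with an estimated correlation). Their sum was 314 ± 105 CPM in GrnKO and 894 ± 755 CPM in WT (exact permutation p = 0.0152, adjusted 0.0606 over 16 sums). WT animal 1 alone held 2346 CPM. B cell markers (camera adjusted p = 0.0116, adjusted p = 0.279 with an estimated correlation) and oligodendrocyte markers (camera adjusted p = 0.0350, adjusted p = 0.485 with an estimated correlation) had positive medians of 0.59 and 0.36. These calls ended without animals 2, 3 or 7 and without animals 3, 5, 6, 7, 8, 9, 11 or 12 (adjusted p of up to 0.133 and 0.135 over the alternatives). The type I interferon (0.0730), MHC class II (0.571), complement (0.128), cytokine (0.616), cholesterol synthesis (0.608), autophagy (0.220), NRF2 (0.0617) and senescence (0.936) lists did not pass the camera test, with the adjusted p in brackets.

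Of the 46 genes called in the low bin, 33 changed at least 2-fold. In all, 1437 genes had an unadjusted p under 0.05, where 704 would by chance. With library size as the only scaling, which shifts the median gene of at least 10 CPM to -0.14 from -0.01, 48 genes were called, 29 higher and 19 lower (60.4% higher against 82.6%). Of the 25 named genes that passed, 15 did so without each animal in turn. Those that lost the call, among them Atp6v1f, Ctso, Cxcl13, Elmo1, Filip1l, Hpse, Smarca2, Tyrobp and Zfp36l2, did so without at least 1 of animals 2, 3, 4, 5, 6, 7, 9, 10, 11 and 12 (adjusted p of at most 0.140). A fit of the low libraries alone called 21 genes. It ended the calls of Atp6v0d2, Ccl8, Ftl1 and those just named except Tyrobp (adjusted p of up to 0.210). The count was 116 without animal 1, 30 without animal 4 and 120 without the 4 libraries highest in choroid plexus markers.

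**Figure D2:**
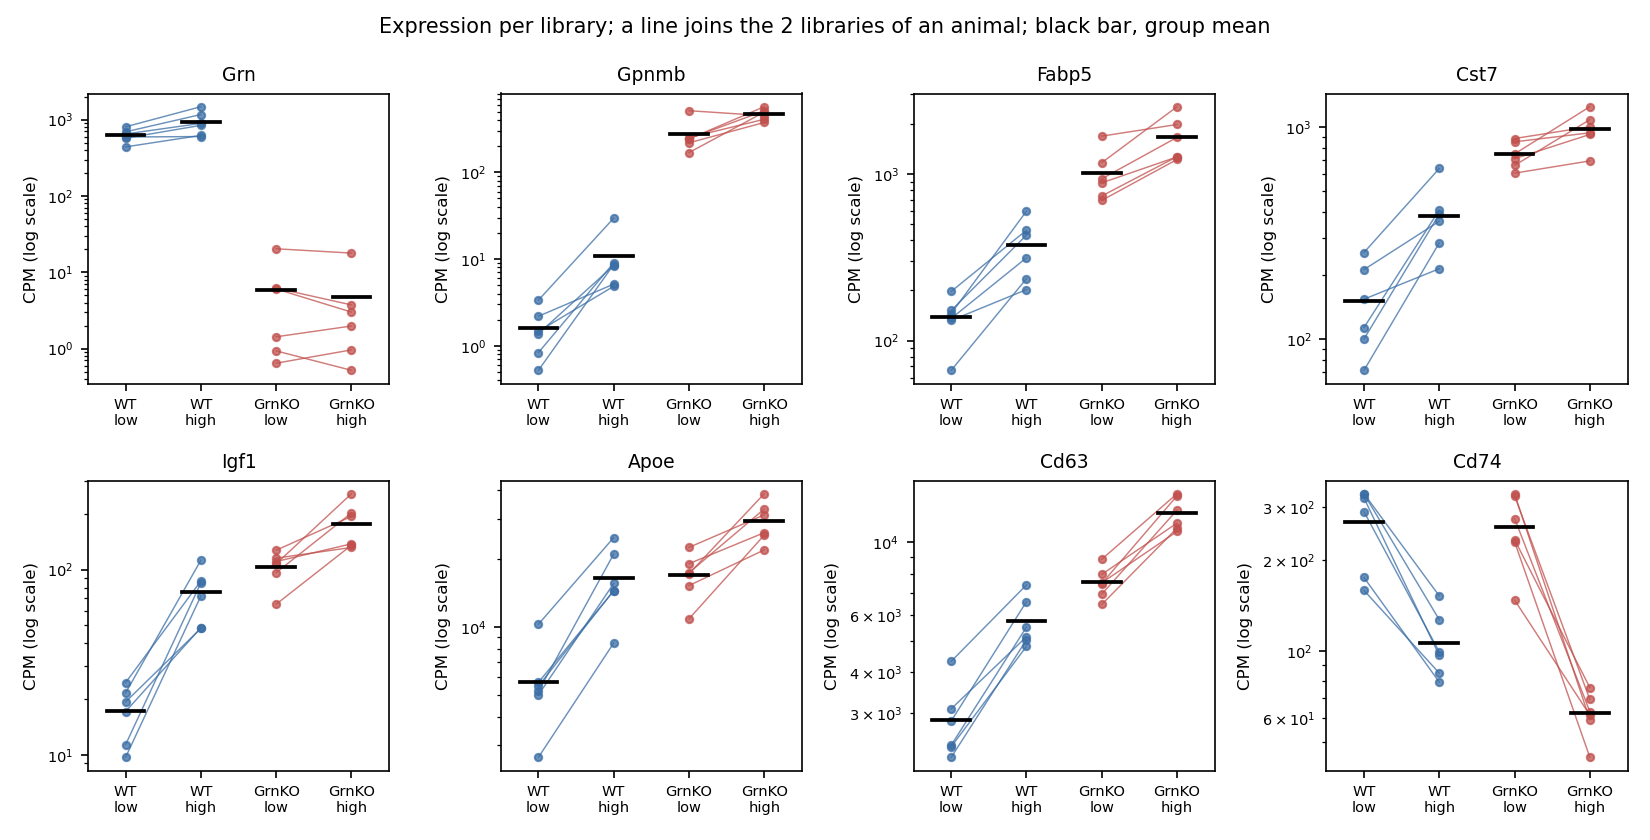
CPM (log scale) of Grn, Gpnmb, Fabp5, Igf1, Cst7, Cd63, Apoe and Cd74 in each library of the 4 groups, with a line joining the 2 libraries of an animal and a black bar at the group mean. Grn lies at 0.520 to 20.3 CPM in GrnKO and 439 to 1477 CPM in WT, and mean Gpnmb goes from 1.62 CPM in WT low to 469 CPM in GrnKO high.

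In the high bin, the cells with most autofluorescence, 19 genes rose and 4 fell in GrnKO. Gpnmb was again the largest rise (469 ± 71.6 CPM in GrnKO high against 11 ± 9.32 CPM in WT high, log2FC 5.54, SE 0.416, edgeR adjusted p = 5.44e-09). Fabp5 stood at 1654 ± 522 against 373 ± 150.3 CPM (log2FC 2.18, SE 0.190, adjusted p = 7.33e-08) and Gpx3 at 296 ± 82.9 against 22.7 ± 12.9 CPM (log2FC 3.66, SE 0.658, adjusted p = 0.0129). Lgals3, a galectin that binds damaged lysosomes, rose (1195 ± 401 against 383 ± 145 CPM, log2FC 1.64, adjusted p = 0.00274), as did the secreted Wfdc17 (1101 ± 423 against 357 ± 106 CPM, log2FC 1.61, adjusted p = 0.00147). Ms4a7, a macrophage membrane protein (591 ± 149.9 against 194 ± 57.2 CPM, log2FC 1.59, adjusted p = 0.00274) and Cox6a2, a subunit of cytochrome c oxidase (507 ± 145 against 192 ± 93.2 CPM, log2FC 1.43, adjusted p = 0.0187).

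Of the 32 disease-associated genes, 7 rose and 0 fell, or 22 up and 1 down when adjusted over the list alone (camera adjusted p = 9.96e-41, adjusted p = 0.000494 with an estimated correlation), with a median of 0.83. Cst7 (982 ± 185 against 382 ± 144 CPM, log2FC 1.38, adjusted p = 0.0120) and Cd63 (12293 ± 1433 against 5742 ± 1028 CPM, log2FC 1.103, adjusted p = 0.000105) were among them. The summed list was 127307 ± 16631 CPM in GrnKO and 77411 ± 12981 CPM in WT (exact permutation p = 0.00216, adjusted 0.0346 over 16 sums). Lysosomal genes had 2 of 45 that rose (10 adjusted over the list alone; camera adjusted p = 2.59e-11, adjusted p = 0.0696 with an estimated correlation). They were Cd63 and Ctsb (15379 ± 2183 against 6904 ± 2074 CPM, log2FC 1.15, adjusted p = 0.0199). V-ATPase subunits had 0 past the threshold over all genes and 6 adjusted over the list alone, with positive folds in 16 of 18 (camera adjusted p = 1.29e-10, adjusted p = 0.000494 with an estimated correlation). Atp6v1g1 stood at 1317 ± 97.1 against 901 ± 88.5 CPM (adjusted p = 0.0615) and Atp6v0c at 1619 ± 188 against 912 ± 278 CPM (adjusted p = 0.125). Autophagy and TFEB pathway genes were positive in 21 of 26, median 0.26, with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00204, adjusted p = 0.0171 with an estimated correlation). Gabarap, a protein of the autophagosome membrane, stood at 640.1 ± 126 against 421 ± 73.6 CPM (adjusted p = 0.306). The glycolysis and hypoxia list had 1 that rose (4 adjusted over the list alone; camera adjusted p = 5.23e-05, adjusted p = 0.0997 with an estimated correlation). It was the mitophagy receptor Bnip3 (239 ± 73.5 against 122 ± 19.5 CPM, log2FC 0.95, adjusted p = 0.0219). The ferritin Fth1 rose by 0.71 on the log2 scale (adjusted p = 0.00391). BMP and ganglioside genes had a median of 0.24 (camera adjusted p = 0.0146, adjusted p = 0.346 with an estimated correlation). This call ended without animal 11 (adjusted p = 0.0652). Cell cycle (camera adjusted p = 0.00251, adjusted p = 0.346 with an estimated correlation) and ribosomal protein genes (camera adjusted p = 0.0281, adjusted p = 0.518 with an estimated correlation) had medians of 0.60 and 0.09. The ribosomal call ended without animals 2, 5, 7 or 11 (adjusted p of up to 0.364 over the alternatives). The LXR and lipid list passed upward with 1 called member, Fabp5, and 3 adjusted over the list alone (camera adjusted p = 0.0403, adjusted p = 0.0823 with an estimated correlation). Its median, though, was -0.10 and its mean 0.03. The call ended without animals 4, 5, 7, 8, 9, 11 or 12 (adjusted p of up to 0.112 over the alternatives).

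Genes that fell in the high bin included Cxcl13 (9.75 ± 6.52 against 207 ± 117 CPM, log2FC -4.44, adjusted p = 0.0492; in limma-voom 0.156 without a block and 0.156 with the animal as a random block). Of 24 immediate-early genes, which respond within minutes to stimulation or handling, 1 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 1.02e-09, adjusted p = 0.00541 with an estimated correlation). The median was -0.65, and the called gene was the transcription factor Egr1 (13.6 ± 8.98 against 52.9 ± 24.6 CPM, log2FC -1.89, adjusted p = 0.0479). The summed list was 1671 ± 315 CPM in GrnKO and 2741 ± 627 CPM in WT (exact permutation p = 0.00649, adjusted 0.0462 over 16 sums). Interferon response genes were negative in all but 5 of 34, median -0.60, with 1 that fell (camera adjusted p = 5.23e-05, adjusted p = 0.0819 with an estimated correlation). It was Ifi27l2a (184 ± 29.9 against 384 ± 173 CPM, log2FC -1.05, adjusted p = 0.0364). The homeostatic list had a median of -0.21, with 0 past the threshold over all genes and 2 down adjusted over the list alone (camera adjusted p = 0.000339, adjusted p = 0.183 with an estimated correlation). Upk1b stood at 75.9 ± 17.3 against 173 ± 73.5 CPM (adjusted p = 0.208).

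Among markers of other cell types, the astrocyte list was lower in GrnKO high with a median of -1.87, 0 past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 1.23e-05, adjusted p = 0.130 with an estimated correlation). Its sum was 312 ± 51.4 CPM in GrnKO and 779 ± 789 CPM in WT (exact permutation p = 0.00866, adjusted 0.0462 over 16 sums), with 2378 CPM in WT animal 1. Choroid plexus markers had a median of -2.70 (camera adjusted p = 0.000438, adjusted p = 0.243 with an estimated correlation). Endothelial markers (camera adjusted p = 0.0117, adjusted p = 0.479 with an estimated correlation) had a median of -1.18. It did not pass without animals 1, 2, 4 or 9 (adjusted p of up to 0.254 over the alternatives). The monocyte (camera adjusted p = 0.0437, adjusted p = 0.346 with an estimated correlation), T and NK cell (camera adjusted p = 0.0168, adjusted p = 0.410 with an estimated correlation) and oligodendrocyte (camera adjusted p = 0.0392, adjusted p = 0.479 with an estimated correlation) calls had medians of 0.74, 0.77 and -0.21. Each ended in limma-voom without a block (camera adjusted p = 0.171, 0.0503 and 0.0756), and adding the animal as a random block changed little (0.169, 0.0504 and 0.0710). They also ended without animals 1, 2, 7, 11 or 12 for monocyte, without animals 2, 4, 5 or 12 for T and NK cell and without animals 1, 2, 3, 4, 6, 7, 9, 10 or 11 for oligodendrocyte markers.

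In all, 23 genes were called, 20 of them changed at least 2-fold, and 888 had an unadjusted p under 0.05 (704 by chance). The count was 45 in limma-voom, both without a block and with the animal as a random block, and 61 without the 4 libraries highest in choroid plexus markers. With library size as the only scaling 14 were higher and 7 lower (66.7% higher against 82.6%). Of the 16 named genes that passed, Cd63, Fabp5, Fth1, Gpnmb, Grn, Lgals3, Ms4a7 and Wfdc17 did so without each animal in turn. Bnip3, Cox6a2, Cst7, Ctsb, Cxcl13, Egr1, Gpx3 and Ifi27l2a lost the call without at least 1 of the 12 animals (adjusted p of at most 0.223). A fit of the high libraries alone called 29 genes and ended the calls of Egr1 (adjusted p = 0.144) and Ifi27l2a (0.0545). The count was 50 without animal 1, 8 without animal 2, 10 without animal 3, 13 without animal 6 and 12 without animal 7.

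**Figure D3:**
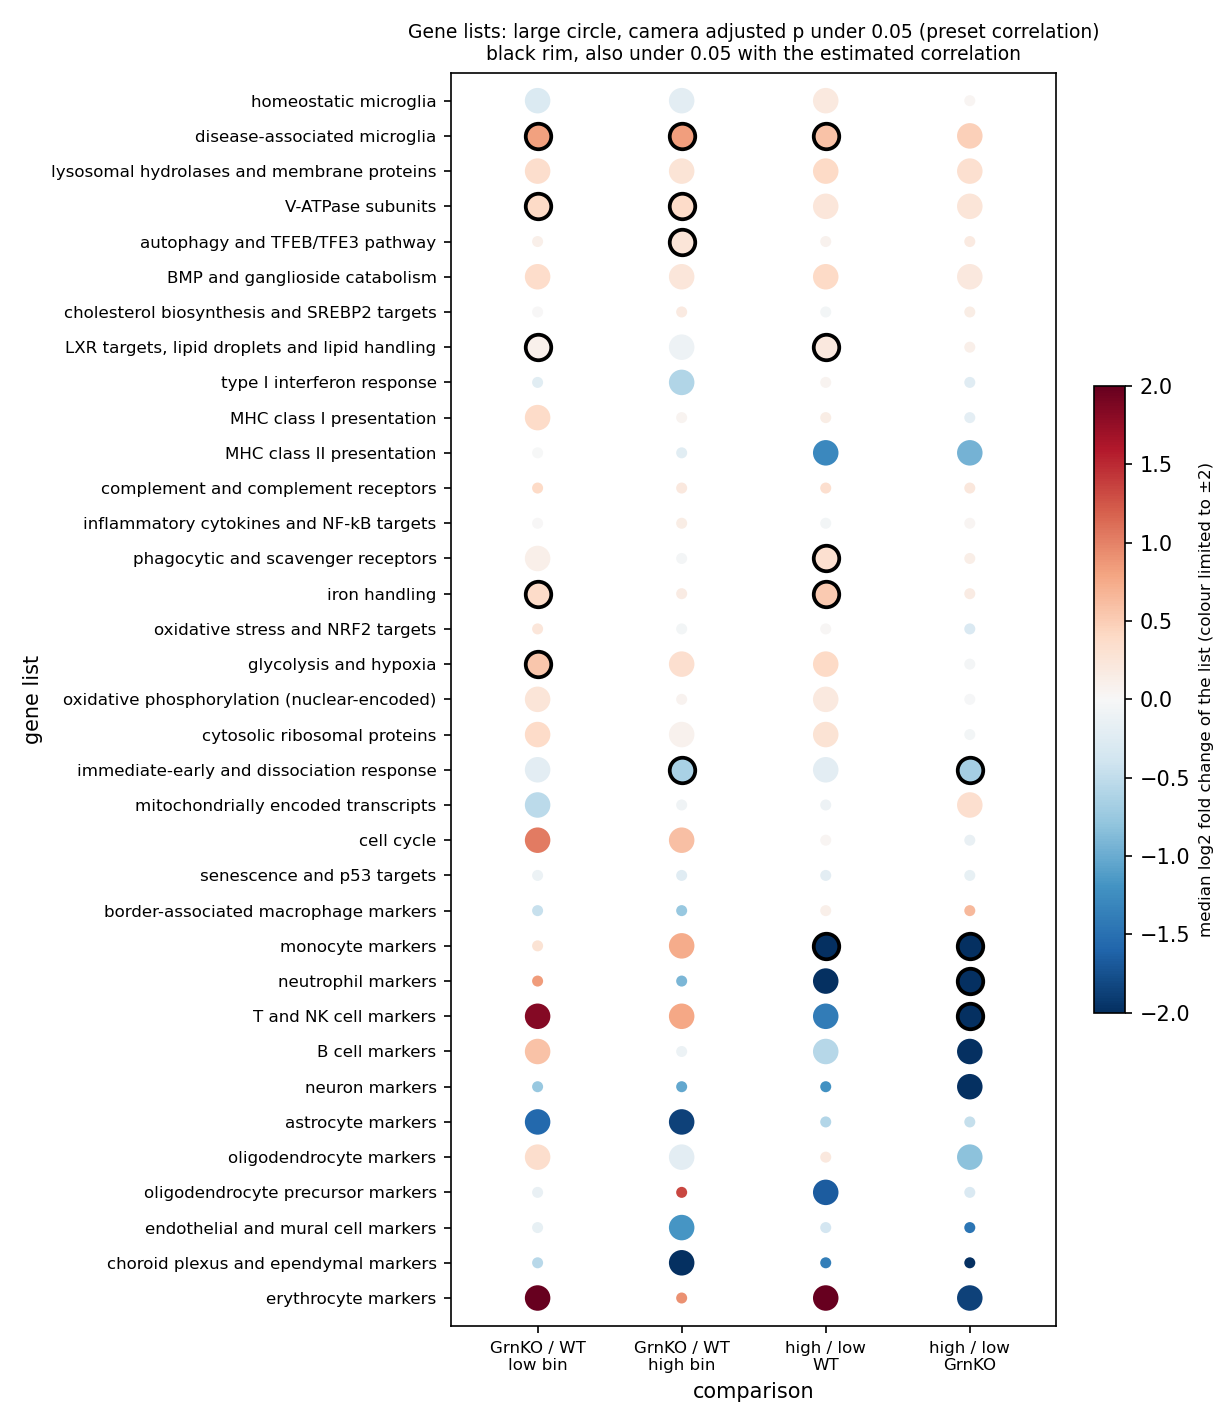
Each circle is 1 of 35 gene lists in 1 of 4 comparisons, coloured by the list's median log2 fold change (limited to ±2), large where the camera adjusted p is under 0.05 and rimmed where this holds with an estimated correlation too. Large circles number 20, 18, 19 and 14 and rimmed ones 5, 4, 5 and 4 in the genotype comparisons of the low and high bin and the lipofuscin comparisons of WT and GrnKO.

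The second question was how microglia with much lipofuscin differ from those with little in the same brain. In WT, 14 genes rose and 21 fell in the high bin (n = 6 animals, each giving both libraries). Gpnmb stood at 11 ± 9.32 CPM in WT high against 1.62 ± 1.02 CPM in WT low (log2FC 2.65, SE 0.374, edgeR adjusted p = 0.000570). In edgeR the call held with the animal as a fixed block (adjusted p = 0.000472). In limma-voom it ended at a similar log2FC, 2.77 without a block (adjusted p = 0.217), 2.76 with a random block (adjusted p = 0.159) and 2.72 with a fixed block (adjusted p = 0.323). Spp1, the secreted glycoprotein osteopontin, rose (2684 ± 676 against 738 ± 466 CPM, log2FC 2.02, SE 0.292, edgeR adjusted p = 0.000671). So did Igf1 (75.4 ± 24.7 against 17.3 ± 5.80 CPM, log2FC 2.09, SE 0.226, edgeR adjusted p = 1.51e-05), Apoe (16427 ± 5691 against 5709 ± 2485 CPM, log2FC 1.52, SE 0.237, edgeR adjusted p = 0.00205) and Fabp5 (373 ± 150.3 against 138 ± 42.2 CPM, log2FC 1.38, SE 0.185, edgeR adjusted p = 0.000444). Among genes that fell, Ly6c2, a surface marker of inflammatory monocytes, went from 121 ± 59.8 to 3.02 ± 3.28 CPM (log2 fold change -5.30, adjusted p = 0.00606; in limma-voom 0.0842 without a block and 0.0657 with the animal as a random block).

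Of 32 disease-associated genes, 7 rose and 0 fell (19 adjusted over the list alone; camera adjusted p = 1.90e-26, adjusted p = 0.00402 with an estimated correlation), with a median of 0.58. They included Cst7 (382 ± 144 against 152 ± 71.1 CPM, log2FC 1.31, adjusted p = 0.0166) and Cd63 (log2FC 1.00, adjusted p = 0.000570). Trem2, the lipid receptor of microglia, stood at 3139.7 ± 733 against 1786 ± 483 CPM (adjusted p = 0.0584). Lysosomal genes had 1 of 45 that rose, Cd63, and 7 adjusted over the list alone (camera adjusted p = 2.07e-10, adjusted p = 0.0643 with an estimated correlation), with positive folds in 39. V-ATPase subunits had a median of 0.25 and 0 past the threshold over all genes, 1 adjusted over the list alone (camera adjusted p = 0.00319, adjusted p = 0.0643 with an estimated correlation). Phagocytic and scavenger receptors were positive in 18 of 22, with 0 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 9.38e-05, adjusted p = 0.00495 with an estimated correlation). Iron-handling genes had 1 that rose, Fth1 (log2FC 0.57, adjusted p = 0.0283), and 5 adjusted over the list alone (camera adjusted p = 0.00163, adjusted p = 0.0359 with an estimated correlation). The LXR and lipid list had 2, Apoe and Fabp5, and 2 adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.0361 with an estimated correlation). The call was lost without animal 5 (adjusted p = 0.0703). The chemokine Ccl8 (185 ± 98.6 against 33.5 ± 20.1 CPM, log2FC 2.47, adjusted p = 0.0192) and the membrane protein Tmem106a (81.2 ± 19.3 against 40.3 ± 7.79 CPM, log2FC 1.02, adjusted p = 0.0333) rose outside these lists. The homeostatic list also passed upward, with a median of 0.19, 0 members past the threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0440, adjusted p = 0.418 with an estimated correlation). This call ended without animals 1, 3, 7 or 9 (adjusted p of up to 0.578 over the alternatives). Positive medians with a camera call were found for BMP and ganglioside (0.40, camera adjusted p = 0.00371, adjusted p = 0.239 with an estimated correlation) and glycolysis (0.40, camera adjusted p = 0.00319, adjusted p = 0.197 with an estimated correlation). The same held for oxidative phosphorylation (0.20, camera adjusted p = 0.00568, adjusted p = 0.478 with an estimated correlation) and ribosomal protein genes (0.29, camera adjusted p = 2.96e-06, adjusted p = 0.197 with an estimated correlation).

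Leukocyte and antigen presentation genes were among those that fell. Of 14 monocyte markers, 5 fell over all genes and 14 adjusted over the list alone, with a median of -4.08 (camera adjusted p = 6.21e-31, adjusted p = 2.15e-05 with an estimated correlation). Among them were S100a6 (66.3 ± 45.2 against 479 ± 174 CPM, log2FC -2.88, adjusted p = 0.00454), S100a4 (6.77 ± 5.03 against 109.9 ± 88.2 CPM, log2FC -4.03, adjusted p = 0.00298; in limma-voom 0.0842 without a block and 0.0569 with the animal as a random block) and Plac8 (3.15 ± 2.98 against 202 ± 227 CPM, log2FC -5.96, adjusted p = 0.0192; in limma-voom 0.129 and 0.0926, in the same order). Of 12 neutrophil markers, 1 fell and 5 adjusted over the list alone (camera adjusted p = 1.31e-10, adjusted p = 0.0517 with an estimated correlation). Ly6g was 2351-fold lower from pooled counts of 2 against 3934 (95% exact interval 650.4 to 19419, counting error only) and lower in 4 of 6 animals (adjusted p = 0.0410; in limma-voom 0.382 without a block and 0.283 with the animal as a random block). Trem3, a receptor of myeloid cells (0.143 ± 0.281 against 23 ± 18.4 CPM, log2FC -7.10, adjusted p = 0.0234), fell. Emb (3.24 ± 4.76 against 66.2 ± 23 CPM, log2FC -4.56, adjusted p = 0.0294) and the integrin Itgal (1.21 ± 1.37 against 35.3 ± 24 CPM, log2FC -4.65, adjusted p = 0.0261; in limma-voom 0.0842 and 0.0567, in the same order) fell. With the animal as a fixed block in edgeR, Ly6c2, S100a4, Plac8, Ly6g and Itgal passed (adjusted p = 0.0109, 0.000245, 0.00300, 0.00300 and 0.0140). Runx3, a transcription factor of lymphocytes, had 0 counts in all 6 WT high libraries, at least 109-fold lower than its 10.9 ± 10.5 CPM in WT low when set against 3 counts per library (adjusted p = 0.0148; 0.0721 with the animal as a fixed block in edgeR). It was lower in 5 of 6 animals. T and NK cell markers had a median of -1.40, 0 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 2.00e-05, adjusted p = 0.183 with an estimated correlation). MHC class II genes, which present antigen, had 1 that fell over all genes. It was the invariant chain Cd74 (107 ± 28 against 268 ± 79.8 CPM, log2FC -1.32, adjusted p = 0.00510). Adjusted over the list alone, 1 rose and 5 fell (camera adjusted p = 6.96e-05, adjusted p = 0.197 with an estimated correlation). Immediate-early genes had a median of -0.22, with 3 down adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.215 with an estimated correlation). It did not pass without animals 5 or 7 (adjusted p of up to 0.0555 over the alternatives). Erythrocyte markers had a median of 7.50, with 0 past the threshold over all genes and 5 up adjusted over the list alone (camera adjusted p = 0.00371, adjusted p = 0.277 with an estimated correlation). The call ended without animal 3 and in limma-voom (camera adjusted p = 0.506 without a block, 0.499 with the animal as a random block), and held with a fixed block in edgeR (camera adjusted p = 0.000744). B cell markers (camera adjusted p = 0.0440, adjusted p = 0.418 with an estimated correlation) had a median of -0.56. The call was lost without animals 1, 5, 9 or 11, with the animal as a fixed block in edgeR (camera adjusted p = 0.0726) and in limma-voom (0.0633 without a block, 0.0654 with a random block). Oligodendrocyte precursor markers (camera adjusted p = 0.0466, adjusted p = 0.197 with an estimated correlation) had a median of -1.67. This call ended without animals 1, 3, 7, 9 or 11 (adjusted p of up to 0.198 over the alternatives).

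Of the 35 genes called, 30 changed at least 2-fold, and 1162 had an unadjusted p under 0.05 (704 by chance). The animal as a fixed block in edgeR gave 64 genes. In limma-voom the count was 36 without a block and 57 with the animal as a random block. With library size as the only scaling 10 were higher and 25 lower (28.6% higher against 40%). Of the 21 named genes that passed, Apoe, Cd63, Fabp5, Gpnmb, Igf1, S100a4 and Spp1 did so without each animal in turn. The other 14 did not pass without animal 3 (adjusted p of at most 0.246 over all animals). A fit of the WT libraries alone called 7 genes. In it Fabp5, Igf1 and Spp1 passed, but Apoe (log2FC 1.53, adjusted p = 0.0959), Cd63 (1.01, adjusted p = 0.0516), Gpnmb (2.62, adjusted p = 0.507) and S100a4 (-4.04, adjusted p = 0.0995) did not. Nor did Ccl8, Cd74, Cst7, Emb, Fth1, Itgal, Tmem106a and Trem3 (adjusted p of up to 0.350). The count was 53 without animal 1, 7 without animal 3, 17 without animal 5, 23 without animal 7, 18 without animal 11 and 82 without the 4 libraries highest in choroid plexus markers.

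In GrnKO, 4 genes rose and 25 fell in the high bin, again with antigen presentation and leukocyte genes among those that fell. Cd74 fell from 258 ± 69.1 to 62.4 ± 10.5 CPM (log2 fold change -2.04, SE 0.229, edgeR adjusted p = 3.06e-05), lower in 6 of 6 animals. The MHC class II chains H2-Eb1 (429.5 ± 167 against 1866 ± 422 CPM, log2FC -2.16, SE 0.358, edgeR adjusted p = 0.0107) and H2-Aa (486 ± 129 against 1858 ± 627 CPM, log2FC -1.96, SE 0.408, edgeR adjusted p = 0.0437) fell with it. The 4 genes that rose were Ms4a7 (591 ± 149.9 against 228 ± 83.7 CPM, log2FC 1.38, SE 0.251, edgeR adjusted p = 0.0150) and its relative Ms4a6d (250.4 ± 39.7 against 144 ± 18.7 CPM, log2FC 0.80, adjusted p = 0.04997, just under the threshold), Cd48, a leukocyte adhesion ligand (662 ± 125 against 389 ± 68.7 CPM, log2FC 0.76, SE 0.144, edgeR adjusted p = 0.0196), and Cd63 (12293 ± 1433 against 7536 ± 838 CPM, log2FC 0.71, SE 0.139, edgeR adjusted p = 0.0261). Each of these 7 genes moved in its direction in 6 of 6 animals.

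MHC class II genes had 4 of 10 that fell (4 adjusted over the list alone; camera adjusted p = 1.23e-09, adjusted p = 0.0609 with an estimated correlation), with a median of -0.94. Monocyte markers had 3 of 14 that fell and 12 adjusted over the list alone (camera adjusted p = 8.64e-27, adjusted p = 2.08e-05 with an estimated correlation), median -3.21. They were S100a6 (104.4 ± 71.7 against 618 ± 298 CPM, log2FC -2.57, adjusted p = 0.0150), S100a4 (12.2 ± 3.83 against 139 ± 70.3 CPM, log2FC -3.49, adjusted p = 0.0150) and Ly6c2 (8 ± 5.24 against 191 ± 186 CPM, log2FC -4.67, adjusted p = 0.0207). Neutrophil markers had a median of -4.93, with 0 past the threshold over all genes and 10 adjusted over the list alone (camera adjusted p = 1.06e-17, adjusted p = 0.00912 with an estimated correlation). Lcn2, an iron-chelating protein of neutrophil granules, stood at 10.6 ± 19.3 against 438 ± 423 CPM (adjusted p = 0.199). T and NK cell markers had 11 adjusted over the list alone and 0 over all genes, median -2.64 (camera adjusted p = 3.77e-16, adjusted p = 0.00873 with an estimated correlation). B cell markers had 7 and 0, median -3.21 (camera adjusted p = 7.45e-07, adjusted p = 0.0633 with an estimated correlation). Anxa1, a phospholipid-binding protein of leukocytes (7.83 ± 7.63 against 101.2 ± 84.6 CPM, log2FC -3.79, adjusted p = 0.04997), Itgal (1.73 ± 1.93 against 34.2 ± 30.7 CPM, log2FC -4.27, adjusted p = 0.04997; in limma-voom 0.0726 without a block and 0.0547 with the animal as a random block) and Mgl2, a lectin of dendritic cells and macrophages (4.76 ± 3.66 against 41.4 ± 34.5 CPM, log2FC -3.12, adjusted p = 0.0412; in limma-voom 0.151 and 0.1001, in the same order), fell. With the animal as a fixed block in edgeR, Itgal and Mgl2 passed (adjusted p = 0.0383 and 0.00811). The kinase Mapk13 was 1010.5-fold lower from pooled counts of 3 against 2760 (95% exact interval 345 to 4903, counting error only). The keratin Krt80 was 637-fold lower from pooled counts of 3 against 1740 (95% exact interval 218 to 3092, counting error only) (adjusted p = 0.0150 and 0.0451; 0.0715 for Krt80 with the animal as a fixed block in edgeR). Ccdc88c was 361-fold lower from pooled counts of 6 against 1970 (95% exact interval 165 to 984, counting error only) (adjusted p = 0.0484). Immediate-early genes were lower in all but 4 of 24, 2 over all genes and 6 adjusted over the list alone (camera adjusted p = 1.23e-09, adjusted p = 0.00873 with an estimated correlation), median -0.68. They were the transcription factors Fos (56.6 ± 28.7 against 183 ± 69 CPM, log2FC -1.78, adjusted p = 0.0108) and Klf2 (51 ± 15.6 against 156 ± 63.7 CPM, log2FC -1.59, adjusted p = 0.0150).

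The disease-associated list passed upward at the preset correlation, with 1 of 32 called, Cd63, and 12 adjusted over the list alone (camera adjusted p = 2.08e-11, adjusted p = 0.0609 with an estimated correlation), median 0.48. Apoe stood at 29390.3 ± 6131 against 16988 ± 3866 CPM (adjusted p = 0.228) and Fabp5 had a log2FC of 0.70 (adjusted p = 0.155). Lysosomal genes were positive in 39 of 45, with 1 that rose and 8 adjusted over the list alone (camera adjusted p = 1.45e-09, adjusted p = 0.0796 with an estimated correlation). V-ATPase subunits had a median of 0.25 (camera adjusted p = 0.00469, adjusted p = 0.0796 with an estimated correlation) and BMP and ganglioside genes of 0.21 (camera adjusted p = 0.0269, adjusted p = 0.383 with an estimated correlation). The latter call ended without animals 6, 8 or 10 (adjusted p of up to 0.161 over the alternatives). Mitochondrially encoded transcripts (camera adjusted p = 0.0162, adjusted p = 0.588 with an estimated correlation) had a median of 0.33. Oligodendrocyte (camera adjusted p = 0.00182, adjusted p = 0.330 with an estimated correlation), neuron (camera adjusted p = 0.0162, adjusted p = 0.175 with an estimated correlation) and erythrocyte markers (camera adjusted p = 0.0155, adjusted p = 0.383 with an estimated correlation) had medians of -0.82, -2.20 and -1.87. The mitochondrial and neuron calls ended without animal 2 and the erythrocyte call without animal 8 (adjusted p of up to 0.115, 0.461 and 0.135 over the alternatives).

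Of the 29 genes called, 26 changed at least 2-fold, and 1102 had an unadjusted p under 0.05 (704 by chance). The animal as a fixed block in edgeR gave 48 genes. In limma-voom the count was 66 without a block and 105 with the animal as a random block. With library size as the only scaling 1 was higher and 27 lower (3.57% higher against 13.8%). Only Cd74 of the 18 named genes that passed did so without each animal in turn. The other 17 lost the call without at least 1 of animals 2, 3, 4, 5, 6, 7, 8, 9, 10, 11 and 12, with adjusted p of at most 0.253. The count was 62 without animal 1, 2 without animal 2, 3 without animal 4, 2 without animal 6, 4 without animal 8, 10 without animal 10, 2 without animal 12 and 57 without the 4 libraries highest in choroid plexus markers.

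**Figure D4:**
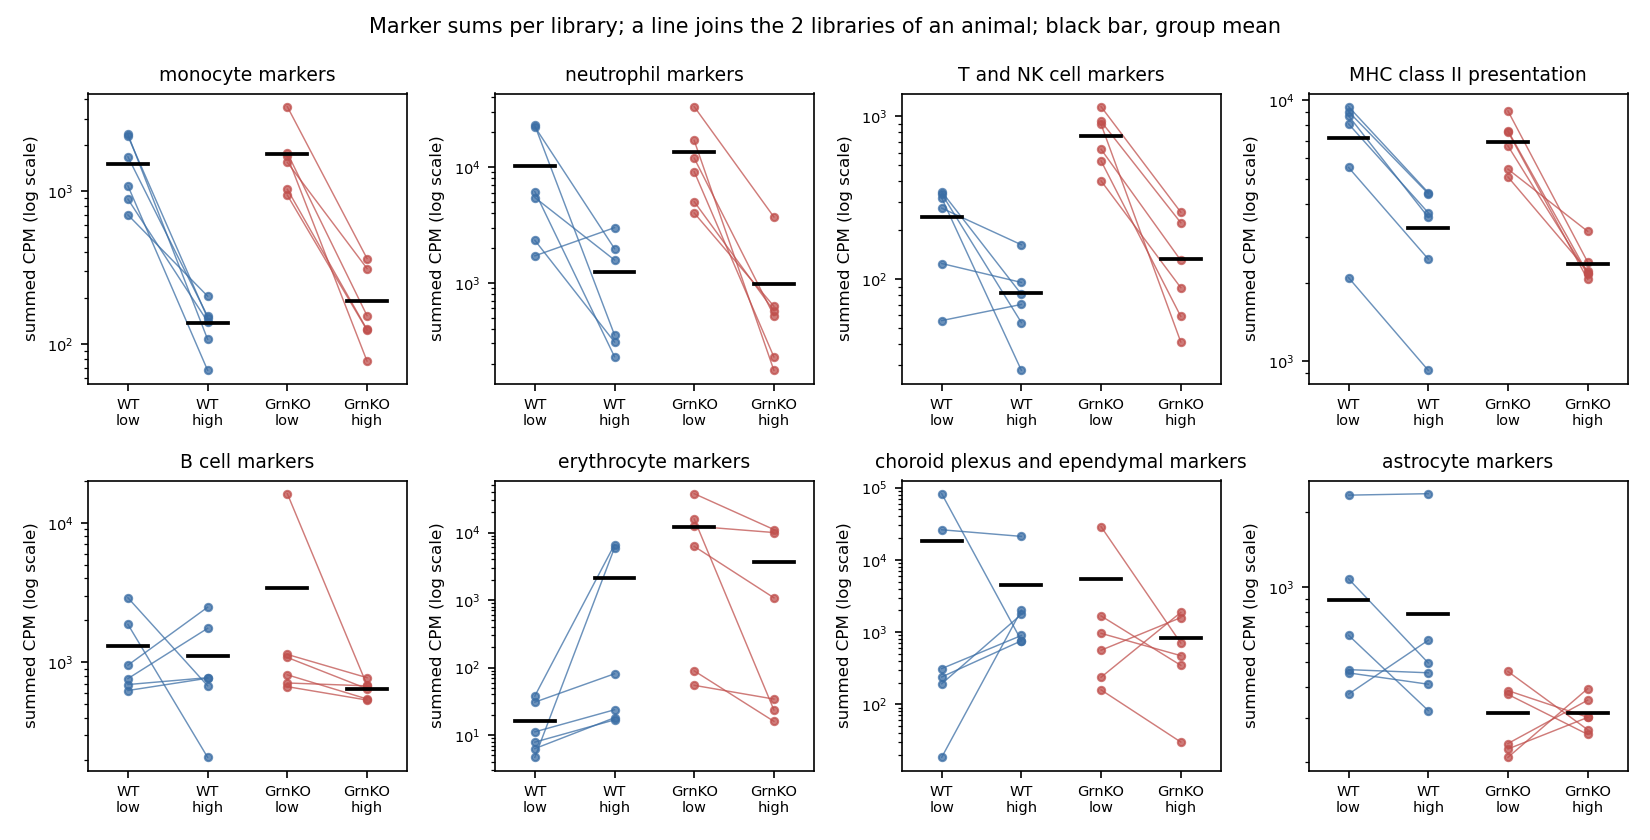
Summed CPM (log scale) of 8 marker lists in each library, with a line joining the 2 libraries of an animal and a black bar at the group mean. Monocyte and MHC class II sums are lower in the high library of 12 of 12 animals.

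The comparisons were then set against each other. The genotype effects in both bins rest on different libraries of the same 12 animals, so they are not independent. They shared 14 genes that rose (Cd63, Cox6a2, Cst7, Ctsb, Fabp5, Fth1, Gm1673, Gng12, Gpnmb, Gpx3, Igf1, Lgals3, Syngr1 and Wfdc17; 0.0512 for independent lists). They shared 2 that fell (Cxcl13 and Grn; 0.00227). Their fold changes correlated across 7211 genes with r = 0.339 (SE over animals left out 0.0528). The lipofuscin effects in WT and GrnKO shared Cd63 among genes that rose (0.00397 for independent lists) and 8 genes that fell, Anxa1, Cd74, Gpr141, Itgal, Ly6c2, S100a11, S100a4 and S100a6 (0.0373), with r = 0.377 (SE 0.0837). Genes are not independent replicates in these correlations.

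Of the 14 genes that rose with lipofuscin in WT, 12 also rose with genotype in the low bin: Apoe, Ccl8, Cd63, Creg1, Cst7, Fabp5, Fth1, Gpnmb, Igf1, Rptoros, Spp1 and Ssr4. Independent lists would share 0.0378. Both effects use the WT low libraries. In 20 simulations of unchanged groups with shared controls 0 genes were called for genotype, so their 0 shared genes decide nothing. Across 7211 genes the fold changes correlated with r = 0.430 against 0.4999 in the simulations. Their covariance was 0.271 against 0.164. With the controls split, so that the lipofuscin effect came from animals labelled male and the genotype effect from animals labelled female, 9 and 25 genes rose and 3 rose in both (Fabp5, Gpnmb and Igf1). In the reverse split 2 and 12 rose and Igf1 rose in both. The correlation across genes was then 0.0369 (SE 0.0642) and 0.0111 (SE 0.0800), so the 2 effects were not correlated measurably over all genes where no library was shared.

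Whether the lipofuscin effect differed between genotypes was tested as an interaction. edgeR called 0 genes (smallest adjusted p 0.786), with 738 at an unadjusted p under 0.05 where 704 would be by chance. DESeq2 called 74 and limma-voom 1, the interleukin receptor Il1r1 (log2FC 10.15, adjusted p = 0.00549). Gpnmb, which rose with genotype by 7.36 in the low and 5.54 in the high bin on the log2 scale, had an interaction of -1.82 (SE 0.497, adjusted p = 0.786). For Fabp5 it was -0.68 (SE 0.257, adjusted p = 0.819). Camera called 8 of 35 lists for the interaction with the preset correlation, 1 up and 7 down, 0 with an estimated correlation, and fry called 0. In simulated data the interaction test recovered 37.3% of genes changed 4-fold and 86.4% of those changed 16-fold. Smaller differences were not detectable in most of the simulated genes.

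Whether the genotype effect differed between the labelled sexes was tested in 8 groups of 3 animals. In the low bin 2 of 16248 genes passed and 1743 had an unadjusted p under 0.05 (812 by chance). Fcgr2b, the inhibitory receptor for immunoglobulin G, had an interaction of -4.40 (SE 0.335, edgeR adjusted p = 3.88e-08). It stood at 172 ± 29 CPM in WT animals labelled male and 896 ± 197 CPM in WT animals labelled female. It was 703 ± 131 CPM in GrnKO animals labelled male and 175 ± 14.3 CPM in GrnKO animals labelled female in the low bin. Abhd12, a serine hydrolase of lysophosphatidylserine, had an interaction of -5.36 (SE 0.675, adjusted p = 0.000333). It stood at 8.07 ± 5.99 CPM in WT animals labelled male and 55.6 ± 20.3 CPM in WT animals labelled female. It was 77.3 ± 21.3 CPM in GrnKO animals labelled male and 13.1 ± 7.10 CPM in GrnKO animals labelled female. In the high bin edgeR called 0 genes (smallest adjusted p 0.413; 1056 at an unadjusted p under 0.05, 812 by chance; 362 in DESeq2). There, Fcgr2b had an interaction of 1.36 (adjusted p = 0.6246). DESeq2 called 660 genes in the low bin, and limma-voom with the animal as a random block 5. Because the sex labels oppose the sex-linked transcripts, these signs follow the labels, not the sex of the animals.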

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

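The gap rule and the interaction tests were fixed beforehand, and the library measures and marker sums on which the gap rule ran were among the tests chosen after the data were seen. Of 200 groups of 6 libraries checked, 37 had a library whose gap to its neighbour exceeded the critical value of Dixon's ratio, where about 10 would by chance at 1 in 20. Of these, 16 were library measures or marker sums and 21 single genes.

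WT animal 1 stood apart in both bins. Its mitochondrial share was 9.70% in the low bin (next library 2.96%) and 7.91% in the high bin (next 2.60%). Its low library held 2346 CPM of astrocyte (next 1082) and 5898 CPM of oligodendrocyte markers (next 1657). It also held 189 CPM of oligodendrocyte precursor (next 25.2) and 1825 CPM of endothelial and mural cell markers (next 446). Its high library held 2378 CPM of astrocyte (next 614) and 81.9 CPM of neuron markers (next 19.2). It also held 54.0 CPM of oligodendrocyte precursor (next 14.3) and 21095 CPM of choroid plexus markers (next 2006). Single genes there were 734 CPM of Ifi27l2a (next 336) and 12.4 CPM of Emb (next 3.89).

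Choroid plexus markers also reached 82298 CPM in WT low animal 9 (next 26053) and 28740 CPM in GrnKO low animal 8 (next 1671). Markers of B cells reached 16189 CPM in GrnKO low animal 2 (next 1140.0). Animal 12 had the most monocyte, neutrophil, and T and NK cell markers of GrnKO low and of GrnKO high, with 3584 CPM of monocyte markers in GrnKO low (next 1786) and 3703 CPM of neutrophil markers in GrnKO high (next 627). Endothelial and mural cell markers reached 269.5 CPM in GrnKO high animal 6 (next 106).

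Single genes in GrnKO low stood apart as well. Fos reached 323 CPM and Ly6c2 553 CPM in animal 12 (next 166 and 215). Others were Gpnmb at 514 CPM in animal 2 (next 252), Grn at 20.3 CPM in animal 4 (next 6.21), and H2-Aa at 3024 CPM and Mgl2 at 107 CPM in animal 10 (next 1900 and 42.5). In GrnKO high they were Grn at 17.9 CPM in animal 4 (next 3.74) and Cxcl13 and Anxa1, each at 22.8 CPM in animal 12 (next 9.24 and 7.92). H2-Eb1 stood at 759 CPM in animal 8 (next 418) and Ccdc88c at 0.132 CPM in animal 8 (next 0.0372). In WT low they were Cxcl13 at 473 CPM in animal 11 (next 132) and Plac8 at 657 CPM and Hpse at 4.497 CPM in animal 5 (next 187 and 0.432). The others there were Atp6v0d2 at 0.432 CPM in animal 9 (next 0.0473) and Smarca2 at 38.6 CPM in animal 7, the lowest of its group (next 61.5). In WT high they were Gpnmb at 29.6 CPM in animal 5 (next 9.04), Trem3 at 0.715 CPM in animal 9 (next 0.0565) and Ly6g at 0.0480 CPM in animal 11 (next 0).

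Effects that differed between groups by a test of the difference were the sex comparisons of Fcgr2b (-4.40) and Abhd12 (-5.36) in the low bin, with 3 animals per group. The genotype by lipofuscin interaction of 8 lists passed camera at its preset correlation. The lists of disease-associated microglia (adjusted p = 0.00261, median -0.26), glycolysis and hypoxia (0.0233, median -0.41), cytosolic ribosomal proteins (1.31e-05, median -0.36) and immediate-early genes (0.0243, median -0.29) were lower. So were T and NK cell markers (0.0221, median -1.24), oligodendrocyte markers (0.00112, median -0.62) and erythrocyte markers (1.002e-05, median -9.12). Mitochondrially encoded transcripts (0.0310, median 0.47) were higher. Lower means that the change from low to high was lower in GrnKO than in WT; the erythrocyte list turned from a rise in WT (median 7.50) to a fall in GrnKO (median -1.87). With an estimated correlation the adjusted p of these lists lay between 0.499 and 0.765. The erythrocyte list had 0.0826 in limma-voom without a block and 0.0822 with the animal as a random block, and passed with a fixed block in edgeR (2.50e-08). The calls of glycolysis (without animals 2, 3, 7 or 12), immediate-early (2, 3, 9 or 12), mitochondrial (2, 3, 7, 9 or 10) and T and NK cell lists (3, 7 or 10) ended when an animal was left out, with adjusted p of up to 0.0898, 0.144, 0.144 and 0.245 over the alternatives.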

How the results depend on the processing

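The alternatives that refine counts, weight libraries, drop libraries high in choroid plexus markers, block by animal in limma-voom as a fixed term, or change the correlation of effects were tests chosen after the data were seen. Counts below are genes called for the genotype effect in the low and the high bin, the lipofuscin effect in WT and GrnKO, and their interaction, in this order (46, 23, 35, 29 and 0 as reported). The cause of a change was not tested unless stated. Close to these were size factors of DESeq2 (52, 25, 38, 28 and 0), library size only (48, 21, 35, 28 and 0), no sex covariate (46, 18, 34, 20 and 0) and refined counts (51, 20, 36, 25 and 0). No filter gave 313, 284, 299, 360 and 329 of 33764 genes, of which 242, 241, 227, 303 and 121 were among the 14090. The stricter filter gave 78 in the first comparison, where fewer genes were tested. Fitting only the groups compared leaves fewer libraries and gave 21, 29, 7 and 61. DESeq2 gave 361, 192, 263, 302 and 74, and in simulated data for the first comparison it made 77 false calls where edgeR made 6 and limma-voom 9. limma-voom gave 65, 45, 36, 66 and 1. With quality weights it gave 81, 113, 83, 198 and 1. On log2 of the deposited CPM plus 1 the counts were 71, 37, 57 and 71, and with 0.1 added lipofuscin in GrnKO had 62 and the interaction 1. Without the 4 libraries high in choroid plexus markers they were 120, 61, 82 and 57.

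With the animal as a random block, limma-voom gave 66, 45, 57, 105 and 1, so beside limma-voom without a block mainly the lipofuscin counts moved. As a fixed block the lipofuscin counts were 64 and 48 in edgeR and 129 and 177 in limma-voom, and the interaction had 0 in both. Set against the same tool without a block, the fixed block in edgeR ended the calls of Runx3, Krt80 and the B cell list in the lipofuscin comparisons and no other call of 39 named genes and 41 lists compared. In limma-voom neither block ended a call of these named genes and lists that limma-voom without a block kept: the random block added 2 genes and 1 list, the fixed block 9 genes and 4 lists. The other losses given beside blocked values came with the change of tool. Leaving out each animal in turn gave 30 to 116, 8 to 50, 7 to 53, 2 to 62 and 0 to 0 genes. In the sex comparison of the low bin (2 genes), no filter gave 330, DESeq2 660 and the random block 5; in the high bin (0 genes), no filter gave 116 and DESeq2 362. Lists called numbered 20, 18, 19, 14 and 8 and, with an estimated correlation, 5, 4, 5, 4 and 0; leaving out an animal gave 4 to 10 for the interaction. With genes of at least 1 CPM the correlations of effects were -0.0292 for the first control split (0.0369 as reported), 0.279 for both lipofuscin effects (0.377) and 0.234 for both genotype effects (0.339).

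Of 2152 comparisons of 80 results of named genes with an alternative, 1787 kept the call, 365 lost it and 0 reversed; the log2 fold change of Grn ranged from -7.84 to -6.54 in the low and -8.94 to -7.48 in the high bin when an animal was left out. Of 2126 comparisons of 79 list calls, 1887 kept the call, 238 lost it and 1 reversed (the mitochondrial list in the low bin, without the libraries high in choroid plexus markers; signed -log10 adjusted p 0.182). Depth was 12.9 to 46.8 M counts, so genes with few counts are measured less well. The deposited rounding to 2 digits limits each count to within 5%, and refining it moved values of 100 or more by a median of 0.455%.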

Other observations

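The tests of the sex labels, of the share of microglia, of blood leukocytes, of GrnKO low against WT high, and of sex structure were chosen after the data were seen. The correlation of MHC class II sums, the control split and the regroupings were written before their results. Several list sums differed from low to high (exact sign-flip tests over 12 animals, adjusted over 16 sums). Border-associated macrophage markers rose in 12 of 12 (mean log2 0.60, SD 0.339, adjusted p = 0.00130). So did homeostatic (0.40, SD 0.291) and disease-associated sums (0.70, SD 0.259), at the same adjusted p. Abundant genes weigh most in sums, and camera called the first list in neither genotype, the second only in WT. Within 1 genotype, 6 animals allow no exact p below 0.0313. Erythrocyte markers were higher in the high library in 6 of 6 WT animals (3.70) and lower in 6 of 6 GrnKO animals (-2.84; exact p = 0.0313 in each, adjusted 0.0625 in WT and 0.05 in GrnKO, neither under the threshold).

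Between GrnKO low and WT high, 30 genes were called (edgeR), 26 higher and 4 lower in GrnKO low. Of the 12 genes that rose with both genotype and lipofuscin, Gpnmb (log2 fold change 4.72, adjusted p = 8.14e-08) and Fabp5 (1.48, adjusted p = 0.000128) were higher in GrnKO low. Cst7 was next, at 743 against 382 CPM (1.00, SE 0.251, adjusted p = 0.0867). Apoe stood at 16988 against 16427 CPM (0.05, adjusted p = 0.995) and Igf1 at 103.6 against 75.4 CPM (0.50, adjusted p = 0.493).

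The sex-linked transcripts opposed the label in 24 of 24 libraries. A random mix-up of animals is argued against, since random labels with 6 animals of each sex would oppose all 12 with an exact chance of 0.00108. A sex column reversed for every animal is a candidate explanation and holds for all 24; no biological explanation was tested.

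Leukocyte and MHC class II transcripts were lower in the high bin. If it raises all other cells' markers alike, a lower microglia share in the low gate is argued against as the leukocyte fall's whole cause. The CD45 gate need not pass those cells alike. From low to high the monocyte sum fell by a log2 of 3.31 (SD 0.828), the neuron, glia and vessel sum by 0.18 (SD 0.474). The fall was larger for monocytes in 12 of 12 animals (exact sign-flip p = 0.000488, the smallest that 12 animals allow). That pooled sum is mostly oligodendrocyte markers (mean 1664 CPM, against 27.3 CPM for neuron markers) and hides lists that fell more. Neuron markers fell by 1.60 (SD 1.03, adjusted p = 0.00130) in 12 of 12 animals, and endothelial and mural cell markers by 0.84 (SD 1.83) in 10 of 12 (exact p = 0.138). These go with a lower share. Against each of the 5 lists alone, monocyte markers fell more in 11 or 12 of 12 animals. Neuron markers came closest (mean difference 1.71, SD 1.47, exact p = 0.00244). A lower share in part, or by leukocytes alone, stays open. For the MHC class II transcripts it is not excluded: 2 of 5 lists (astrocyte and oligodendrocyte) fell less than their sum at an exact p under 0.05, but neuron markers did not (mean difference 0.26 the other way, SD 1.03, exact p = 0.386). Blood leukocytes in the low gate, which the CD11b and CD45 gate would keep in part, may account for the fall of leukocyte markers and stay open. Of the leukocyte sums, 3 of 4 were lower at an exact p under 0.05. They were monocyte at -3.31, neutrophil at -3.63 (exact p = 0.000977) and T and NK cell at -2.09, but not B cell markers (exact p = 0.174). Whether the same cells carried the MHC class II transcripts, whose sum fell in 12 of 12 animals by 1.34 (SD 0.371, adjusted p = 0.00130), cannot be told apart from a change within microglia. Over 12 low libraries their sum correlated with that of monocyte and B cell markers at rho = 0.280 (permutation p = 0.378, adjusted 0.566 over 3 relations) and r = 0.206 (p = 0.456; 0.0450 without the 2 farthest libraries). It was rho = 0.657 in WT and 0.2 in GrnKO (exact p = 0.175 and 0.714).

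Disease-associated microglia genes were higher with both lipofuscin and loss of Grn. Chance deviations of the WT low libraries that both comparisons share are argued against. With controls split by labelled sex, 4 of 4 medians (0.78 and 0.58 for lipofuscin, 0.76 and 1.15 for genotype) lay above the central 95% of 1000 random lists (upper ends 0.46, 0.32, 0.43 and 0.36). That GrnKO low cells resemble WT cells with up to the lipofuscin of the WT high bin could explain part of these genes and stays open. Of 12 shared genes, 2 (Gpnmb and Fabp5) were called higher in GrnKO low than in WT high, under the bound of 3 genes, set after the data were seen, for arguing against it. The outcome rests on that bound. Without gate limits per genotype, a direct genotype effect within a bin cannot be told apart from a shift of lipofuscin within it.

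Other groupings tested if chance gives as many genes, though the real effect widens their spread. For the genotype effect, 1 of 100 regroupings, the real one, called as many genes in the low bin (46, highest other 1) and in the high bin (23, highest other 1). Chance is argued against there. For lipofuscin in WT (35 genes) and GrnKO (29 genes), the real grouping, which parts every pair, alone called as many among 32 groupings that do so and among 69 (itself and those that keep some pairs together). The highest others, 1 in WT and 0 in GrnKO, argue against chance too. It cannot be excluded for the sex comparison in the low bin (2 genes; 5 of 100, highest other 3). For the interaction and the sex comparison in the high bin, edgeR called 0 genes, so 100 of 100 regroupings call at least as many whatever the data (highest other 1 in each), and the test decides nothing there. At an unadjusted p under 0.05 they had 738 and 1056 genes, and DESeq2 called 74 and 362.

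The sex comparisons of Fcgr2b and Abhd12 had the other sign in the high bin, where neither passed. There Fcgr2b stood at 692 ± 208 CPM in WT animals labelled male and 981 ± 109 CPM in WT animals labelled female, and 265 ± 38.7 CPM in GrnKO animals labelled male and 983 ± 24 CPM in GrnKO animals labelled female (n = 3; interaction 1.36, edgeR adjusted p = 0.6246). Abhd12 stood at 358 ± 154 CPM in WT animals labelled male and 211 ± 12.1 CPM in WT animals labelled female, and 16.2 ± 2.71 CPM in GrnKO animals labelled male and 101.6 ± 34.2 CPM in GrnKO animals labelled female (n = 3; interaction 3.39, edgeR adjusted p = 0.413). Of 7034 genes over 10 CPM on average and over 1 CPM in more than 0.8 of libraries (deposited CPM), 28 passed an unadjusted p of 0.001 for a dependence on labelled sex that differs between groups, where 7.03 would by chance. A set of 100 permutations of the labels within groups gave a median of 4 and a highest of 37 (permutation p = 0.0198).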
